A study of Drosophila melanogaster with 4 samples.

How the data were processed

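Small RNAs were sequenced from Drosophila Schneider 2 (S2) cells, an embryonic cell line, in which the gene for the exonuclease Nibbler (Nbr) had been removed by CRISPR-Cas9. One library came from the knockout cells (nbrKO) and 3 from knockout cells stably carrying a construct under the Act5C driver: Nbr(wt), NbrCTD or NbrCTD-GWp. The labels do not spell out CTD or GWp, so the constructs carry their label names here. Each of the 4 groups held 1 library. Per the labels' protocols, cells grew at 25 °C, libraries were made from 25 µg of total RNA cut to 18 to 30 nt and depleted of 2S rRNA, and both adapters carried 4 random bases at the ligated ends. Random bases there lessen ligation bias at the miRNA 3′ end, and nothing in the sources used here says that they served to remove PCR duplicates.

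The analysis began from the authors' deposited table of 495 rows, 1 for each 5′ isoform of a miRNA arm. The submitters' processing notes name cutadapt 1.2.1 and HTSeq 0.9.1 without saying what each did. Aligner, counting rule and genome build are not given in the sources used here. Per the file headers, the authors gave each library 2 columns in RPM, one headed GM and one headed PM. The headers do not spell these out. They were read as reads that match the genome over their whole length and as prefix-matching reads, whose 5′ part matches and whose 3′ end carries an untemplated tail. A deposited fraction (0 to 1) gives the share of an arm's reads held by the listed 5′ isoform, per the file headers and the values, and a TRUE or FALSE column marks an arm. TRUE was the arm with more reads in 148 of 151 precursors of nbrKO, 134 of 135 with Nbr(wt), 134 of 135 with NbrCTD and 141 of 142 with NbrCTD-GWp. The remaining 4 per-sample columns, a type for each row, were not used.

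In each library nearly every RPM value was a whole multiple of 1 step, the worth of 1 read. Dividing by the step gave whole reads, within 0.01 read, for 94.8% to 95.9% of GM values and 91.7% to 95.2% of PM values above 0. The others were fractions, as arise when reads that fit several loci are split. The steps correspond to totals of 24005045 reads in nbrKO, 32488012 with Nbr(wt), 26500155 with NbrCTD and 27312149 with NbrCTD-GWp. Because some values are fractions, no count model was fitted. Reads were rounded only to compute intervals.

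Rows given in all 4 libraries (270) were joined into 261 miRNA arms by summing loci with the same name and 5′ end. Of 2 names with identical values, 1 was dropped: miR-276a-5p stands for miR-276b-5p too. The miR-2 and miR-13 families are nearly identical at the 5′ end, so tailed reads can be split between them, and their single values are uncertain. Tailed share is PM reads over the sum of GM and PM reads of the leading 5′ isoform. It was computed for the 114 arms with at least 100 reads in every library, and these held over 99% of the reads of the 261 arms in each. Exact Clopper-Pearson intervals at 95% accompany each share. An arm was called lower or higher when the intervals of the 2 libraries did not overlap. Log2 odds ratios used 0.5 reads added to both kinds of read. Abundance was given in miRNA RPM for the 123 arms with a mean of at least 100 reads. It is the RPM of the leading isoform with the library's reads in the 261 arms as the total. Calls needed at least a 2-fold difference on the log2(value + 1) scale, which understates the change of rare arms, and non-overlapping exact Poisson intervals. All intervals cover counting error only.

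The plan, fixed before the data were examined, was to compare mean read lengths. The table holds no read lengths, so that part was not run, and tailed share, planned as the second measure of the 3′ end, took its place, as the rule for named miRNAs foresaw. The rule took, for each construct, the 12 largest falls and 4 largest rises in tailed share in percentage points among arms with non-overlapping intervals, every measured member of the list of reported Nbr substrates, the 5 most abundant miRNAs of nbrKO, and the 4 highest and 4 lowest abundance folds past the threshold. Lists fixed in advance from background knowledge were the reported substrates, the K-box seed family, mirtrons, miRNAs common in S2 cells, the clusters of miR-277, miR-34 and miR-317 and of miR-275 and miR-305, AGO2-loaded miRNAs, markers of other cells with early embryo markers as a part, and arm classes. A guide arm is the arm of a precursor with more reads over all libraries, and a passenger arm is the other. A list's median was set against 10000 random lists of the same size matched on abundance in 5 bins, but not on tailed share in nbrKO. Random lists were drawn from all arms, the list's own members included. With 1 library per group there is no p-value and no replicate check, and every comparison is between libraries.

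The 3 changes against nbrKO share that library, so unchanged libraries were simulated by binomial draws (100 draws) from its tailed shares. With no change, the simulated range of calls ended at 2 of the 114 arms in each direction. The calls were tested on simulated data at the real depths: a 2-fold lower odds of tailing (log2 of -1) was called in 69.0% of arms for the depth of Nbr(wt), 69.5% for NbrCTD and 70.5% for NbrCTD-GWp, and a log2 change of -0.5 in 54.0%, 52.0% and 54.5%. Changes of 1.5 on the log2 scale in abundance, planted in arms below 1% of reads, were called in at least 99.5% of arms in every comparison. Alternatives varied the minimum reads, thresholds, scaling, pseudocount and summary. Positions come from the BDGP6 annotation, matched by gene name for 217 of the 219 precursor names. The table's own positions lay inside the named gene for 117 of 491 rows, nearly all on chromosome arm 2L, so it uses another build and none of its positions is given. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.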

Results

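The data describe miRNA 3′ ends and abundance in S2 cells that lack the 3′-to-5′ exonuclease Nibbler (Nbr), which shortens miRNAs bound to Argonaute, and in the same cells given back 1 of 3 Nbr constructs. The question is how miRNA 3′ ends and abundance with each construct differ from nbrKO. The sample titles call the constructs overexpressed. No library came from S2 cells with Nbr intact or from nbrKO cells with an empty construct. A return to the original level could therefore not be judged, nor could an effect of carrying any construct be set apart. The miRNA rows held 13126126 reads in nbrKO, 20177315 with Nbr(wt), 14786074 with NbrCTD and 17766373 with NbrCTD-GWp. These were 54.7%, 62.1%, 55.8% and 65.0% of the totals behind the deposited RPM values. There is 1 library per group, so no difference below has a replicate check, and intervals cover counting error only. The libraries hold RNA of 18 to 30 nt, so neither Nbr mRNA nor the constructs' expression was measured, and the labels could not be checked in that way. Read lengths were not analysed here. The 3′ end was followed through untemplated tails, the counterpart of trimming at the same end.

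Markers of other cells were rare in all libraries. Of 20 marker arms of muscle, neurons, larval or adult tissue, early embryo, ovary and testis, 15 were measured, and only the ovary marker miR-318-3p and the embryonic miR-6-3p passed 100 reads in every library. The summed level was 243 miRNA RPM (RPM with the reads of the joined miRNA arms as the total) in nbrKO, 171 with Nbr(wt), 156 with NbrCTD and 143 with NbrCTD-GWp. Neither miR-318-3p nor miR-6-3p was called lower or higher in tailed share against nbrKO in any construct's library.

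With wild-type Nbr, most guide miRNAs carried fewer tails than in nbrKO. Of 114 arms, 55 had a lower tailed share and 6 a higher one, and intervals overlapped for 53. The median share was 2.05% against 3.01% in nbrKO. For miR-34-5p, which is linked to ageing and neuronal maintenance in flies, the share was 9.58% (95% interval 9.45 to 9.72) in nbrKO and 3.70% (3.63 to 3.78) with Nbr(wt). For miR-305-5p it was 6.88% and 2.00%, and for miR-317-3p it was 11.3% and 4.68%. The abundant miR-14-3p, a regulator of cell death and metabolism, had 3.46% and 1.60%, and miR-8-3p, the fly member of the miR-200 family, had 6.82% and 3.85%. miR-184-3p had 4.97% and 3.69%, and miR-2b-3p, whose reads can be split with its relatives, had 3.12% and 1.76%. bantam-3p, the growth-promoting miRNA that gave the most reads, did not follow: its share was 0.599% (0.592 to 0.606) in nbrKO and 0.654% (0.648 to 0.660) with Nbr(wt).

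Rankings of falls and rises below cover only arms whose intervals did not overlap, and some arms outside them rose by more without a call. Among the 12 largest falls with Nbr(wt), the heavily tailed miR-1008-3p went from 68.0% to 51.5% and miR-2497-3p, measured on only 181 reads in nbrKO, from 87.8% to 73.4%. miR-31a-5p went from 10.9% (7.78 to 14.8) to 3.27% (1.51 to 6.12), miR-1012-3p from 17.4% to 9.80%, miR-281-3p from 10.5% to 4.15%, miR-1006-3p from 12.7% to 6.44%, miR-965-3p from 9.74% to 4.53% and miR-998-3p from 12.1% to 7.36%. miR-2c-3p went from 14.2% to 6.38%, a value that is uncertain because its reads can be split with its relatives. The 4 largest called rises were those of 3 passenger arms, miR-283-3p (2.89% to 5.01%), miR-190-3p (1.73% to 3.32%) and miR-282-3p (2.07% to 3.41%), and of the guide miR-279-3p (5.80% to 6.84%). These 4 arms were also called higher with NbrCTD and with NbrCTD-GWp.

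With NbrCTD the changes were smaller and went both ways: 37 arms were lower than in nbrKO, 21 were higher, and intervals overlapped for 56. The median share was 2.73%. miR-34-5p stood at 7.32% (7.16 to 7.47) and miR-305-5p at 4.06%, between their values in nbrKO and with Nbr(wt), and so did miR-317-3p at 7.72% and miR-8-3p at 6.0%. The largest called falls included miR-1008-3p (45.4%), miR-2497-3p (68.8%), miR-1012-3p (10.3%), miR-1006-3p (7.40%), miR-965-3p (5.30%), miR-275-3p (8.21% in nbrKO to 4.66%), miR-283-5p (7.14% to 3.92%), miR-995-5p (6.21% to 3.52%), miR-281-2-5p (8.37% to 5.84%) and miR-34-3p (6.26% to 3.75%). The largest called rises were miR-4939-3p (11.1% to 21.3%), miR-1007-3p (20.9% to 29.4%), miR-998-3p (12.1% to 17.1%) and miR-1000-5p (1.82% to 6.07%). Among these, miR-998-3p was lower than nbrKO with Nbr(wt) and higher with NbrCTD, and the direct comparison of both constructs had non-overlapping intervals. Requiring a log2 odds ratio of at least 0.5 leaves 22 lower and 10 higher arms with NbrCTD.

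With NbrCTD-GWp, the pattern lay close to that of wild-type Nbr: 51 arms were lower than in nbrKO, 8 were higher, and intervals overlapped for 55. The median share was 2.25%. miR-34-5p had 3.92% (3.84 to 4.00), miR-305-5p 1.99%, miR-317-3p 5.94%, miR-31a-5p 3.33%, miR-281-3p 5.86%, miR-965-3p 5.11%, miR-1012-3p 9.53%, miR-2c-3p 6.46%, miR-1008-3p 51.4% and miR-2497-3p 64.5%. miR-275-3p lay below both other constructs, at 2.46% against 4.47% with Nbr(wt) and 4.66% with NbrCTD. miR-1007-3p, higher than nbrKO with NbrCTD, was lower with NbrCTD-GWp at 15.6%. The largest called rise was that of miR-12-3p, from 5.37% to 9.61%, ahead of miR-283-3p (5.36%), miR-190-3p (3.08%) and miR-282-3p (2.63%).

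**Figure D1:**
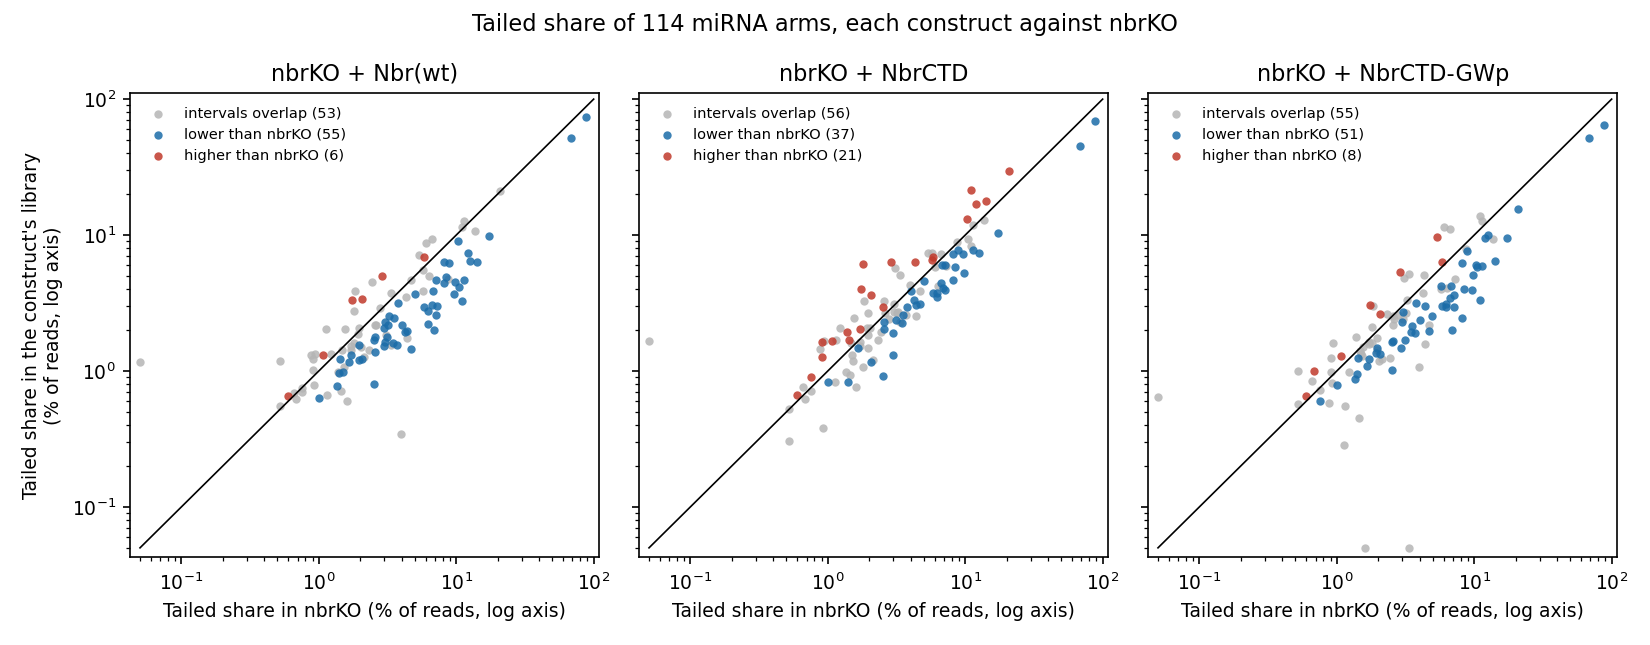
Tailed share of 114 miRNA arms in nbrKO (horizontal, % of reads, log axis) and in each construct's library (vertical, % of reads, log axis); each point is 1 arm coloured by whether exact 95% intervals overlap, and shares below 0.05% are drawn at 0.05%. Below the line of equal shares, with non-overlapping intervals, lie 55 arms with Nbr(wt), 37 with NbrCTD and 51 with NbrCTD-GWp.

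The constructs were also compared with each other, without nbrKO. NbrCTD had a higher tailed share than Nbr(wt) in 45 arms and a lower one only in miR-1008-3p, the 1 exception. NbrCTD-GWp was lower than NbrCTD in 40 arms and higher in 4, miR-1006-3p, miR-1008-3p, miR-2a-2-5p and miR-7-5p. Of these 4, miR-2a-2-5p was named after its values were seen. Against Nbr(wt), NbrCTD-GWp was higher in 23 arms and lower in 12, including miR-184-3p (2.56% against 3.69%). Over the 55 arms lower with Nbr(wt) than in nbrKO, the median share of that fall seen in another construct was 53.4% for NbrCTD (quartiles 32.6% and 77.4%) and 88.8% for NbrCTD-GWp (72.4% and 104%). The ratio was larger for NbrCTD-GWp in 42 of the 55. These 55 arms were chosen by their change with Nbr(wt), and of the 21 arms called higher with NbrCTD than in nbrKO they hold only 6. Both sides of these ratios use the 1 nbrKO library, so a value peculiar to that library would enter every one of them. As a slope through the origin, which weighs large changes most, the value for NbrCTD is 82.5%. None of these values describes all arms. With all miRNA reads pooled, the tailed share with NbrCTD lay close to nbrKO, at 2.64% against 2.72%. It was 1.81% with Nbr(wt) and 1.85% with NbrCTD-GWp.

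Because all changes share the 1 nbrKO library, they correlate over arms without any effect. The log2 odds ratios of Nbr(wt) and NbrCTD had a Pearson r of 0.67 across the 114 arms, which are not independent replicates, inside the range of simulated unchanged libraries (0.15 to 0.74, mean 0.51). For Nbr(wt) and NbrCTD-GWp r was 0.72, also inside its simulated range (0.03 to 0.78, mean 0.50). The covariances, 0.336 and 0.413, lay above their simulated ranges, which hold counting error only and ended at 0.215 and 0.213. Arms called lower in both numbered 37 for Nbr(wt) and NbrCTD, where independent lists would share 17.9, and 47 for Nbr(wt) and NbrCTD-GWp, where they would share 24.6. The numbers for independent lists take every arm as equally easy to call. Arms with more reads are called more easily in every comparison, so some excess arises without any common effect. How much of the excess came from this or from the shared nbrKO library was not determined, since 1 library could not be split.

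The reported Nbr substrates, listed in advance from background knowledge, fell more in tailed share with Nbr(wt) than most random lists of like abundance. The members were recalled as miRNAs trimmed by Nbr, a different measure from tailed share. The list was not checked against published work. Of 10 listed, 7 had enough reads, since miR-3-3p, miR-10-5p and miR-100-5p did not. The median tailed share of the 7 in nbrKO was 6.88%, against 3.01% over all arms. Random lists were not matched on that share, so a low percentile can reflect a high starting share. With Nbr(wt), 5 of the 7 were lower and none was higher, with a median log2 odds ratio of -1.38, at percentile 0.28 among random lists. With NbrCTD 4 were lower, with a median of -0.41 at percentile 11.3. With NbrCTD-GWp 5 were lower and 1 higher, with a median of -1.01 at percentile 3.09. The 5 lower with both were miR-34-5p, miR-11-3p, miR-31a-5p, miR-305-5p and miR-317-3p. miR-11-3p, encoded in an intron of the cell cycle gene E2f1, had 4.02% in nbrKO, 2.17% with Nbr(wt), 3.85% with NbrCTD and 2.37% with NbrCTD-GWp. For miR-263a-5p, at 5.70%, 3.90%, 7.34% and 4.02%, a difference from nbrKO was not detectable at this depth. miR-7-5p carried few tails: 0.684% in nbrKO, 0.618% with Nbr(wt), 0.627% with NbrCTD and 0.992% (0.904 to 1.09) with NbrCTD-GWp, its only call against nbrKO.

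**Figure D2:**
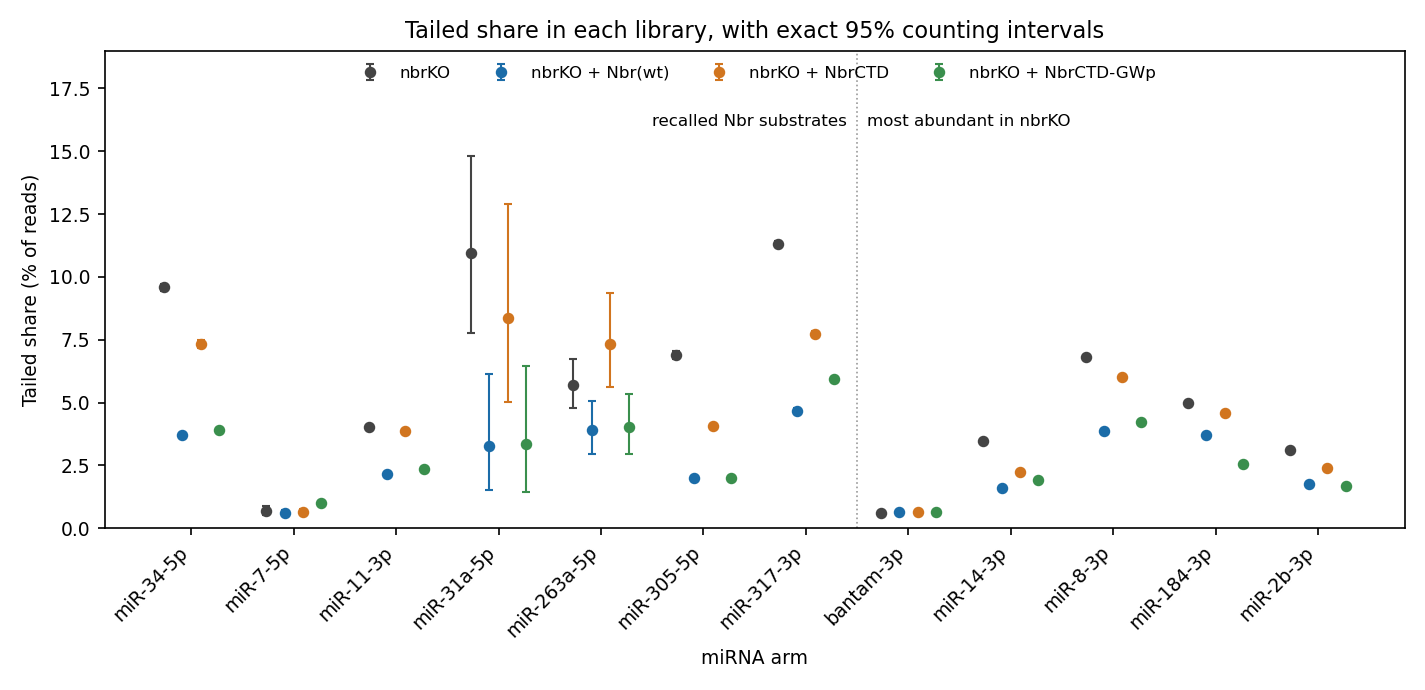
Tailed share (% of reads) of the 7 measured miRNAs recalled as Nbr substrates and the 5 most abundant miRNAs of nbrKO (horizontal) in each of the 4 libraries, with exact 95% counting intervals. miR-34-5p falls from 9.58% in nbrKO to 3.70% with Nbr(wt), 7.32% with NbrCTD and 3.92% with NbrCTD-GWp, while bantam-3p lies between 0.599% and 0.662% in all 4.

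Neighbouring miRNAs of a cluster were examined as groups, and the median of each list was ranked among random lists of the same abundance, where a low percentile means a larger fall. In the cluster of miR-277, miR-34 and miR-317, 5 of 6 arms were lower with Nbr(wt), 3 were lower and 2 higher with NbrCTD, and 5 were lower with NbrCTD-GWp, at percentiles 2.35, 11.03 and 10.3. In the cluster of miR-275 and miR-305, 4 of 4 arms were lower with Nbr(wt), 3 with NbrCTD and 3 with NbrCTD-GWp, at percentiles 6.88, 2.81 and 0.36. Members of both clusters, miR-34-5p, miR-317-3p and miR-305-5p, are also reported substrates, so these results partly repeat those of that list. Mirtrons, whose 3′ ends are made by splicing and are often uridylated by Tailor, had a median tailed share of 11.3% in nbrKO over 9 measured of 14 listed members. They were lower in 4 with Nbr(wt), in 4 with 1 higher with NbrCTD, and in 5 with NbrCTD-GWp, at percentiles 9.47, 83.8 and 53.1. In the K-box seed family, 5 of 8 members were lower and 1 higher with Nbr(wt), 4 lower and 2 higher with NbrCTD, and 5 lower and 1 higher with NbrCTD-GWp, at percentiles 64.4, 56.3 and 27.4. Of these 8, 5 are miR-2 or miR-13 arms whose reads can be split. Of 16 miRNAs common in S2 cells, 11 were lower and 2 higher with Nbr(wt), 6 lower and 9 higher with NbrCTD, and 13 lower and 2 higher with NbrCTD-GWp, at percentiles 80.2, 99.4 and 64.2. The 3 arms recalled as loaded into AGO2, where 2′-O-methylation protects the 3′ end, had a median tailed share of 0.758% in nbrKO. Arms outside this list, such as bantam-3p and miR-7-5p, had lower shares there, so a link to methylation was not shown. Of the 3 AGO2 arms, 1 was lower with Nbr(wt), none was lower and 1 higher with NbrCTD, and 2 were lower with NbrCTD-GWp. Their percentiles were 84.7, 84.7 and 74.6. The medians of mirtrons, the K-box family and the AGO2 list lay inside the range of random lists with each construct, so their counts of lower members do not set them apart.

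By arm class, 34 of 45 guide arms were lower and 3 higher with Nbr(wt), against 17 lower and 3 higher of 46 passenger arms, which have fewer reads and so wider intervals. The median log2 odds ratio was -0.61 for guides and -0.34 for passengers. With NbrCTD, 26 guides were lower and 10 higher, and 10 passengers were lower and 7 higher. With NbrCTD-GWp, 35 guides were lower and 4 higher, and 12 passengers were lower and 4 higher. Over Nbr(wt), NbrCTD and NbrCTD-GWp, guides lay at percentiles 7.02, 0.40 and 1.91 and passengers at 98.25, 65.4 and 99.65. Of 54 arms from the 5′ side of the hairpin, 28 were lower and none higher with Nbr(wt), 19 lower and 4 higher with NbrCTD, and 23 lower and 1 higher with NbrCTD-GWp. Of 60 arms from the 3′ side, 27 were lower and 6 higher, 18 lower and 17 higher, and 28 lower and 7 higher. The percentiles were 35.3, 5.39 and 56.5 for the 5′ side and 81.3, 99.15 and 54.0 for the 3′ side. These classes are so large that random lists repeat many of their members. The 5′ and 3′ sides together make up all arms, and guides and passengers most of them. Opposite percentiles within each pair are therefore not separate results. Guides also started at a higher median tailed share in nbrKO, 4.02% against 2.47% for passengers, and random lists were not matched on it.

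Abundance differed from nbrKO in the same direction for several genomic neighbours. Every fold is against the 1 nbrKO library, so the constructs' folds are not independent of each other. miR-92a-3p and miR-92b-3p, both encoded in jigr1, had 12.6 and 33.4 miRNA RPM in nbrKO, 90.3 and 118 with Nbr(wt), 64.9 and 88.1 with NbrCTD, and 289.9 and 323 with NbrCTD-GWp. The passenger miR-92a-5p went from 6.18 to 65.6 with NbrCTD-GWp. miR-279-3p and miR-996-3p, which restrain neuron formation and come from 1 non-coding transcript, had 4313 and 1415 in nbrKO, 10412 and 4762 with Nbr(wt), 13700.2 and 7551 with NbrCTD, and 9851 and 5217 with NbrCTD-GWp. The passenger miR-980-5p went from 65.3 to 358, 425 and 297. On the lower side, miR-278-5p had 48.9 in nbrKO, 7.69 with Nbr(wt), 5.47 with NbrCTD and 6.20 with NbrCTD-GWp, and its guide miR-278-3p had 1150.4, 314, 223 and 199. miR-281-1-5p had 115.2, 21.9, 24.7 and 32.9, and miR-281-2-5p had 467, 103, 121 and 135. These calls, except that of miR-92a-5p outside NbrCTD-GWp, kept their side of the 2-fold threshold under all 4 scalings tried.

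Of 123 arms, 8 were at least 2-fold higher and 31 lower with Nbr(wt), 11 higher and 19 lower with NbrCTD, and 10 higher and 21 lower with NbrCTD-GWp. The split depends on scaling. Median-of-ratios size factors shift the log2 folds by 0.59, 0.36 and 0.41 and give 20 higher and 13 lower, 21 and 12, and 18 and 12. Trimmed means shift them by 0.78, 0.42 and 0.49 and give 27 and 9, 23 and 11, and 20 and 12. The authors' RPM shifts them by 0.18, 0.04 and 0.25 and gives 11 and 21, 13 and 16, and 12 and 14. With total miRNA reads, 6 arms were higher and 18 lower in all 3 constructs' libraries. All 3 folds use the 1 nbrKO library, so a value peculiar to it would give such agreement by itself. miR-998-5p (776 in nbrKO, 158 with Nbr(wt), 377 with NbrCTD, 328 with NbrCTD-GWp) held its call under every scaling only with Nbr(wt), miR-252-5p (4466, 2081, 2058, 810.2) only with NbrCTD-GWp, and miR-986-3p (19.2, 5.70, 4.70, 2.38) with NbrCTD and NbrCTD-GWp. Of the 8 measured reported substrates, 1 was higher and 1 lower with Nbr(wt), 1 lower with NbrCTD, and 1 higher and 1 lower with NbrCTD-GWp.

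The ratio of passenger to guide arms of the same precursor, which does not depend on scaling, was lower than in nbrKO in most precursors with Nbr(wt). Over 47 precursors, it was lower in 35 and higher in 12 with Nbr(wt), 31 and 16 with NbrCTD, and 27 and 20 with NbrCTD-GWp. Differences of any size were counted. The median log2 changes were -0.64, -0.48 and -0.27, and the quartiles with NbrCTD-GWp were -0.99 and 0.23. The ratio was lower with Nbr(wt) than with NbrCTD in 34 of the 47, and higher with NbrCTD-GWp than with Nbr(wt) in 38. The passenger share of miR-996 reads was 27.0% in nbrKO, 7.78% with Nbr(wt), 6.15% with NbrCTD and 8.31% with NbrCTD-GWp, and that of miR-184 was 10.8%, 3.03%, 4.99% and 3.16%. These 2 precursors were named after their values were seen.

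**Figure D3:**
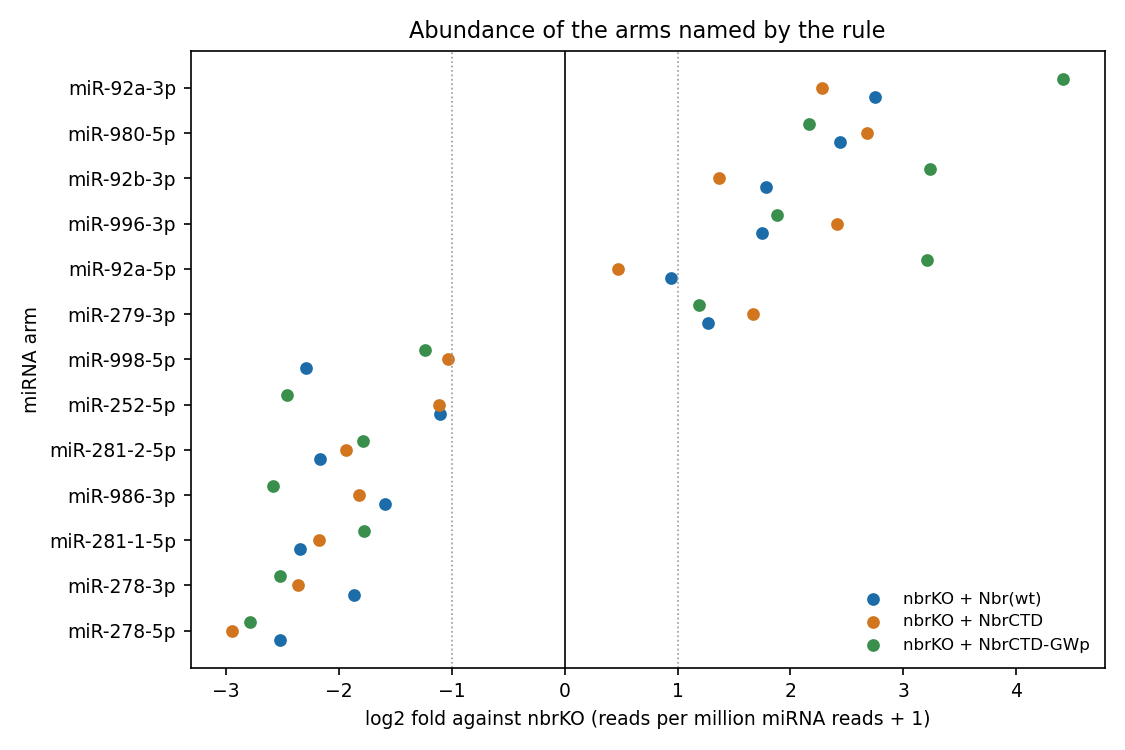
Log2 fold of abundance against nbrKO (miRNA RPM + 1, horizontal) of the 13 arms with the highest and lowest folds past the threshold (vertical), 1 point per construct's library. Dotted lines mark 2-fold, and miR-92a-3p reaches 4.42 with NbrCTD-GWp while miR-278-5p lies at -2.95 with NbrCTD.

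In the BDGP6 annotation, mir-34 lies on chromosome 3R from 10100936 to 10101034 in an exon of a long non-coding RNA, and mir-317 upstream of it from 10091126 to 10091217, outside annotated genes of its strand. mir-275 (2L, 7425795 to 7425892) lies in an exon of a long non-coding RNA and mir-305 (2L, 7425972 to 7426044) beside it. mir-1008 (2R, 10885533 to 10885589) lies in an intron of CG18004, and mir-1012 (3R, 26861349 to 26861407) in one of Lerp. mir-11 (3R, 21622497 to 21622571) and mir-998 (3R, 21621879 to 21622021) lie in an intron of E2f1. mir-92a (3R, 25646506 to 25646600) lies in an intron of jigr1 and mir-92b (3R, 25651398 to 25651497) in one of its exons. mir-279 (3R, 29215585 to 29215684) and mir-996 (3R, 29217184 to 29217280) lie in an exon of the non-coding RNA CR31044, and mir-278 (2R, 15657066 to 15657163) in an exon of CG42524.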

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

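The percentiles of the arm classes and the median-of-ratios scaling were planned, and the other tests in this part, as well as the use of those percentiles against a lower yield, were chosen after the result was seen. The share of an arm's reads held by its leading 5′ isoform entered no comparison above. It was compared for each locus on its own, so miRNAs with several loci count more than once and 88 entries had at least 1000 reads, all 5′ isoforms included, in every library. Of these, 3 had a share at least 10 percentage points above or below nbrKO, with non-overlapping intervals, in some construct's library. For miR-2a-2-5p it was 52.0% in nbrKO, 71.4% with Nbr(wt), 70.6% with NbrCTD and 56.1% with NbrCTD-GWp. For miR-995-5p it was 69.8% in nbrKO, 82.8% with Nbr(wt), 77.8% with NbrCTD and 82.3% with NbrCTD-GWp. For miR-2c-3p it was 91.5% in nbrKO, 92.8% with Nbr(wt), 92.0% with NbrCTD and 80.4% with NbrCTD-GWp. miR-2a-2-5p and miR-2c-3p come from a family that shares reads, and the cause was not tested.

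The lower tailed share with Nbr(wt) and NbrCTD-GWp was set against several explanations, on the 82 arms with at least 1000 reads in every library, and the tables exclude none of them. One factor on every arm's tailed share stays open although the log2 odds ratios had an SD of 0.60 with Nbr(wt), above the 0.312 that counting error gave at most, and so does 1 amount subtracted from every share, with an SD of 2.69 percentage points against at most 0.644. Counting error leaves out the spread between separately prepared libraries, which 1 library per group cannot give. Preparation or depth of single libraries stays open too, since the ranks of all 4 libraries by read total equal their ranks by falling pooled tailed share. Trimming restored to different extents may also account for it, but the changes of Nbr(wt) against nbrKO and of NbrCTD-GWp against NbrCTD, which share no library, correlated with an r of only 0.11 over arms, inside the range of -0.36 to 0.37 without any change, so these explanations cannot be told apart here.

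The passenger arms were lower relative to the guide arms with Nbr(wt) than in nbrKO. Scaling does not account for this, because it leaves the passenger to guide ratio as it is. That ratio is itself the pattern, so its median log2 change of -0.64 is no separate test. The interval of -0.94 to -0.28 resamples precursors of 1 pair of libraries and leaves out the spread between libraries. The level of the passenger arms alone does depend on scaling, with medians of -0.60 by total miRNA reads and -0.01 by median-of-ratios. An unusual nbrKO library stays open: the ratio was also lower with Nbr(wt) than with NbrCTD, by a median of -0.30 (-0.41 to -0.15), but both are single libraries, and NbrCTD-GWp lay above Nbr(wt) by a median of 0.24. A lower yield of every rare miRNA may contribute. The median of the passenger arms lay at percentile 17.0 among arms of the same abundance, inside the random range, while guide arms lay at 98.3. Random lists of this size repeat many members of both classes, so these percentiles cannot decide the point. Variation of the Nbr(wt) library itself could not be examined with 1 library, and no biological explanation was tested.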

How the results depend on the processing

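Alternatives for thresholds on tailing effect size, the arm filters, constructs compared with each other, the authors' RPM and all reads of an arm were chosen after seeing the data, and the others before the data were examined. Of 147 alternative values for 27 results, 100 stayed within 1.5 times the main count or within the counting interval and 47 moved. The balance of higher and lower abundance turned with scaling. Counts of arms lower in tailed share with Nbr(wt) and NbrCTD-GWp than in nbrKO stayed within 1.5 times under every alternative run. Counts between constructs did so too, but they met fewer alternatives. These were other read minima and leaving out the miR-2, miR-13 and several-locus arms. Neither effect size thresholds nor the 5′ isoform filter were applied between constructs. Requiring a log2 odds ratio of at least 0.5 left 3 higher with Nbr(wt), 22 lower and 10 higher with NbrCTD, and 4 higher with NbrCTD-GWp. A difference of at least 1 percentage point left 23 lower and 11 higher with NbrCTD and 3 higher with NbrCTD-GWp, by construction fewer. Pooling all miRNA reads gave tailed shares of 2.72% in nbrKO, 1.81% with Nbr(wt), 2.64% with NbrCTD and 1.85% with NbrCTD-GWp, so the gap between nbrKO and NbrCTD narrowed. The share of the Nbr(wt) fall was 59.9% for NbrCTD and 96.5% for NbrCTD-GWp from summed changes, 82.5% and 105.5% as a slope through the origin, and 38.5% and 93.3% over the reported substrates; the cause was not tested. NbrCTD-GWp stayed above NbrCTD in each. In abundance, with higher and lower counts in this order for Nbr(wt), NbrCTD and NbrCTD-GWp, median-of-ratios size factors gave 20 and 13, 21 and 12, and 18 and 12, and trimmed means 27 and 9, 23 and 11, and 20 and 12. A 1.5-fold threshold gave 16 and 51, 23 and 38, and 18 and 38. A 3-fold threshold gave 5 and 13 with Nbr(wt), 4 and 10 with NbrCTD, and 11 lower with NbrCTD-GWp. Lower counts were 49, 34 and 35 with no minimum, 16, 10 and 10 with a minimum mean of 1000 reads, and 20 for Nbr(wt) with a pseudocount of 10. Every alternative about read length (length thresholds, modal length, share of shorter reads, reads with or without tails) was not run, because the table holds no lengths. Not every change can be called at these depths, since in simulated data a 2-fold lower odds of tailing was called in 69.0% to 70.5% of arms. Which arms were missed was not broken down by abundance or tailed share.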

Other observations

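The tests on 5′ isoforms and on the passenger shares of single precursors were chosen after the values were seen. The calls of tailed share were planned, but grouping arms by their calls over all constructs was not. In 2 arms the leading 5′ isoform itself differed between libraries. miR-2a-2-3p led with the isoform whose seed is TATCACA in nbrKO, at 57.0% of the arm's reads, with Nbr(wt) and with NbrCTD-GWp, and with TCACAGC, which starts 2 nt further on, with NbrCTD at 51.9%, though its family shares reads. For miR-252-3p, CCTGCTG led at 60.4% in nbrKO, 46.5% with Nbr(wt) and 48.4% with NbrCTD. With NbrCTD-GWp TCCTGCT, 1 nt away, held the most reads at 46.7% (41.7 to 51.8), measured on only 398 reads, so the lead there is uncertain. A different 5′ end changes the seed and so the set of possible targets. Across the 89 entries compared, with each locus on its own and miR-252-3p included despite fewer than 1000 reads in 2 libraries, the leading isoform held a median of 96.9% of the reads in nbrKO.

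The passenger to guide ratio was higher than in nbrKO with every construct in 10 of 47 precursors and lower with every construct in 23. These comparisons share the nbrKO library, so they can agree without any effect of the constructs. The 10 include miR-980 and miR-2279. The passenger share of miR-980 reads was 1.28% in nbrKO, 4.08% with Nbr(wt), 3.01% with NbrCTD and 3.51% with NbrCTD-GWp, and that of miR-2279 was 20.4%, 33.9%, 34.5% and 29.8%. For miR-34, miR-12 and miR-2a the ratio was higher than in nbrKO only with NbrCTD and lower with both other constructs. The passenger share of miR-34 was 11.4% in nbrKO, 10.1% with Nbr(wt), 18.4% with NbrCTD and 9.66% with NbrCTD-GWp, and that of miR-12 was 15.0%, 7.92%, 21.3% and 7.70%. That of miR-2a, whose family shares reads, was 14.0%, 12.4%, 24.5% and 11.7%.

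In 6 arms, miR-277-3p, miR-2c-3p, miR-33-5p, miR-980-3p, miR-996-3p and miR-998-3p, the tailed share was higher than in nbrKO with NbrCTD and lower with both other constructs. These arms were grouped after the calls were seen, and all their comparisons share the nbrKO library. The value of miR-2c-3p is uncertain because its reads can be split with its relatives. miR-998-3p had 12.1% in nbrKO, 7.36% with Nbr(wt), 17.1% with NbrCTD and 9.58% with NbrCTD-GWp, and miR-996-3p had 2.54%, 1.68%, 2.97% and 1.62%, with non-overlapping intervals against nbrKO in each case.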
